A study of Homo sapiens with 3 samples.

How the data were processed

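The series holds 3 samples of the LNCaP prostate cancer line, which are ChIP of H3K27ac, ChIP of H3K4me1 and an input library without antibody. Per the labels' protocols, nuclei were taken from formaldehyde-crosslinked cells, chromatin was sonicated, and libraries were sequenced as short single-end reads on an Illumina HiSeq instrument. The labels give 1 sample per mark and no replicate. Bowtie 0.12.8 and the build hg19 are named in the submitters' processing notes. The region caller, its settings, its threshold, the treatment of duplicate reads and whether the input served as background are not given in the sources used here. The choice of caller and threshold sets the number and width of regions, so differences between the lists hold for the lists and may not hold for the marks.

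Each deposited list gives a chromosome, a start, an end and a score per region, without a header. All starts and ends fall on a grid of 50 bp, no regions of a list overlap, and the narrowest region is 550 bp in both lists. The score is the authors' value per region, deposited without a name. It takes 12 values from 0.001 to 0.048 in the H3K27ac list and 13 values from 0.001 to 0.093 in the H3K4me1 list, and is lower in wider regions. It has the range of a false discovery rate, but no source used here states what it is, so it served only to rank or filter regions within a list, with low scores taken as the more stringent. The lists hold no read counts, so depth is unknown. Each list holds 1 mitochondrial region, from position 1 to 17150 for H3K27ac and to 17100 for H3K4me1, which was left out of all lengths, overlaps and densities.

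Gene names were not assigned. The gene table used for names is of another assembly, GRCh38, and coordinates were not converted between builds. The planned comparisons with transcription start sites and with fixed gene lists (androgen response, prostate lineage factors, luminal, basal, mesenchymal, neuroendocrine and other cell types, HOX and further lists) were therefore not run, and no values for them are given. Regions were named by coordinates, as the rule fixed before the data were examined foresaw. That rule named the 15 joined H3K27ac clusters with the greatest covered length, the 5 widest regions per mark, the 3 windows of 1 Mb with the most H3K27ac, the 3 with the most H3K4me1 and no H3K27ac, and the chromosomes of highest and lowest density.

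Starts were read as 0-based, as in BED files, and are printed counted from 1. A region counted as overlapping when it shared at least 1 bp with a region of the other list. Exact Clopper-Pearson 95% intervals were computed over regions. Because neighbouring regions are not independent, these intervals are too narrow and cover counting error only. Chance overlap was the mean of 1000 random circular shifts of the regions within each chromosome, at least 1 Mb long, with 100 shifts for width classes, single chromosomes and alternatives. Chromosome length was the span of both lists, 3093 Mb in all. The shift test was checked on 3 simulated lists of 4000 regions with known overlap: the overlap share was recovered without error, and the shifted mean differed from that of independent placement by at most 0.526 percentage points. The simulated regions lay on 1 chromosome, were of equal width within a list and were placed without clustering. The check therefore covers the computation and not the chance level of clustered lists. The H3K4me1 profile was read at each 50 bp step up to 10 kb from the midpoint, and its dip was bootstrapped over regions with 1000 draws. H3K27ac regions at most 12.5 kb apart were joined into clusters and ranked by the length the regions covered.

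The alternatives fixed before the data were examined were an overlap of at least 50% of the region, scores at or below the list median, merging of regions within 1 kb, leaving out regions under 500 bp, autosomes only, a joining distance of 5 kb, windows of 250 kb, and densities by number of regions. Alternatives added after seeing the data were a score under 0.05 for H3K4me1, removal of region-free stretches of 1 Mb or more before shifting, and a fixed offset of 50 kb. Also chosen after seeing the data were the width classes, the curve of fixed offsets, the midpoint and edge profile with the distance of its maximum, the distance to the nearest H3K4me1 region, the score limit of 0.003, the grouping of windows by covered length and the shifted means of single chromosomes. Because scores are tied, the score at or below the median kept 41860 H3K27ac regions (58.9%) and 101538 H3K4me1 regions (50.6%). Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.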

Results

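ChIP-seq of 2 histone marks was analysed in LNCaP, an androgen-responsive line derived from a metastatic human prostate carcinoma. The marks were H3K27ac, acetylation found at active enhancers and promoters, and H3K4me1, monomethylation found at enhancers whether active or only primed. The series design also names normal prostate epithelial cells and the PC3 cancer line, which were not analysed here. Each mark was represented by 1 library and 1 list of called regions, and the input library was not analysed here. All coordinates are hg19, counted from 1. No replicate spread could be measured, so the intervals below cover counting error over regions only, treating regions as independent. No p-value was computed, and the values describe these 2 lists. The lists carry no read counts, so the sequencing depth behind them is unknown and a region missing from a list cannot be read as absence of the mark.

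H3K4me1 was the more widespread mark. Outside the mitochondrial sequence, 200812 H3K4me1 regions covered 292 Mb, or 9.45% of the chromosome spans, against 71077 H3K27ac regions covering 144 Mb, or 4.65%. The H3K4me1 list therefore held 2.83 times as many regions and 2.03 times the covered length. H3K27ac regions were wider, with a median of 1600 bp (quartiles 1050 and 2400 bp) against 1050 bp (quartiles 750 and 1650 bp) for H3K4me1. The widest H3K27ac region reached 121650 bp and the widest H3K4me1 region 45250 bp. Neighbouring H3K27ac regions were separated by a median of 13600 bp and neighbouring H3K4me1 regions by 4000 bp. The 2 lists ended at different limits of the authors' score, 0.048 for H3K27ac and 0.093 for H3K4me1, and with H3K4me1 regions of a score under 0.05 alone the list held 152493 regions and 261 Mb.

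The next comparison asked how far the active mark coincided with the enhancer mark. Most H3K27ac regions overlapped an H3K4me1 region, whereas most H3K4me1 regions of the full list overlapped no H3K27ac region. Of the 71077 H3K27ac regions, 59040 (83.1%, exact 95% interval 82.8% to 83.3%) overlapped an H3K4me1 region by at least 1 bp. The remaining 12037 regions (16.9%) carried H3K27ac alone. Of the 200812 H3K4me1 regions, 69306 (34.5%, interval 34.3% to 34.7%) overlapped H3K27ac, and 131506 (65.5%) carried H3K4me1 alone. This majority did not hold at the lowest scores. At scores of 0.003 or less, 39674 H3K4me1 regions overlapped H3K27ac and 16133 did not. By length, 103 Mb carried both marks, which was 71.5% of the H3K27ac length and 35.1% of the H3K4me1 length.

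Both overlaps exceeded random placement. In 1000 circular shifts of the regions within each chromosome, a mean of 20.4% of H3K27ac regions (range 19.2% to 21.7%) met H3K4me1, so the observed share was 4.07 times the shifted mean. The corresponding mean for H3K4me1 regions meeting H3K27ac was 8.22% (range 7.77% to 8.75%), a 4.20-fold difference. When at least 50% of the region had to be covered, the H3K27ac fold rose to 7.57. Part of this came from broad neighbourhoods rich in both marks. When the H3K27ac regions were moved by 50 kb in either direction, 31.6% still met H3K4me1, and at 1000 kb 24.7% did. Measured against the offset of 50 kb, a setting chosen after the data were seen, the H3K27ac overlap was 2.62-fold higher than its local level and the H3K4me1 overlap 2.62-fold higher. The overlap fell steeply over the first kilobases, from 83.1% in place to 58.0% at 2 kb and 39.1% at 5 kb.

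Wide regions nearly always carried both marks, and narrow ones did so less often. Among H3K27ac regions under 1 kb, 62.8% (interval 62.1% to 63.6%, 15439 regions) overlapped H3K4me1, against 94.6% (94.3% to 94.9%, 20450 regions) at 2 to 4 kb and 442 of 444 at 10 kb or more. The gradient was steeper for H3K4me1, where 12.6% of regions under 1 kb (12.4% to 12.8%, 89760 regions) overlapped H3K27ac, against 72.2% (71.7% to 72.7%, 28672 regions) at 2 to 4 kb and all 661 regions of 10 kb or more. Width alone raises the chance of an overlap, and the shifted means rose too, from 14.4% to 52.0% for H3K27ac and from 6.58% to 28.5% for H3K4me1. Relative to those means, the H3K4me1 overlap went from 1.91-fold under 1 kb to 6.69-fold at 2 to 4 kb and 3.51-fold at 10 kb or more. The H3K27ac overlap was 4.38-fold under 1 kb and 1.91-fold at 10 kb or more, where the observed share could rise little further.

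**Figure D1:**
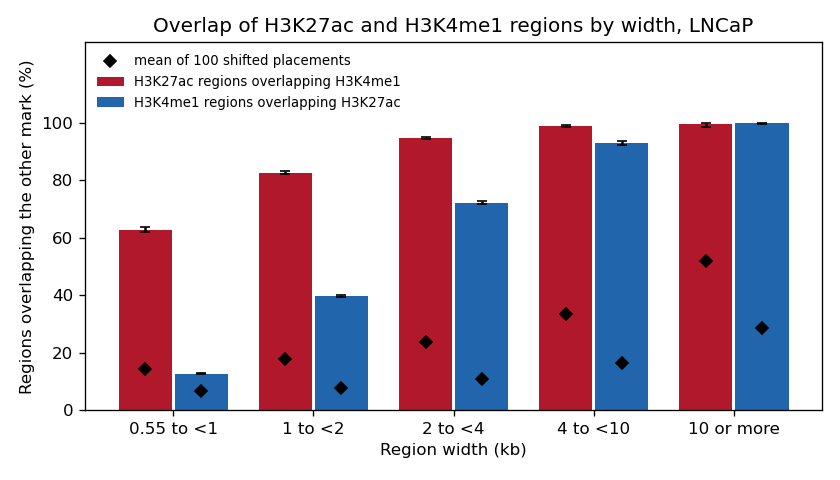
Share of regions overlapping the other mark by region width in kb, for H3K27ac (red) and H3K4me1 (blue) regions of 1 library each. Error bars are exact 95% intervals over regions, and diamonds are the mean of 100 shifted placements. H3K4me1 regions went from 12.6% under 1 kb to 100% at 10 kb or more, and H3K27ac regions from 62.8% to 99.5%.

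Regions with both marks were wider and had lower scores than regions with 1 mark. Wider regions meet the other mark more often by chance too. The width difference is thus the gradient by width read the other way, and was not compared with shifted placements. H3K27ac regions with H3K4me1 had a median width of 1750 bp (quartiles 1150 and 2600 bp), and those alone 1000 bp (700 and 1450 bp). The lowest H3K27ac score, 0.001, was carried by 16.9% of regions with both marks (interval 16.6% to 17.2%) and by 1.37% of those alone (1.17% to 1.59%). H3K4me1 regions with H3K27ac had a median width of 1700 bp (1050 and 2750 bp), and those alone 900 bp (650 and 1100 bp). H3K4me1 scores of 0.003 or less were carried by 57.2% of regions with H3K27ac (56.9% to 57.6%) and by 12.3% of those alone (12.1% to 12.4%). Scores fell with width in both lists, so these differences in width and score are not separate. Of the 12037 regions with H3K27ac alone, 2958 (24.6%) lay within 1 kb of an H3K4me1 region and 3382 (28.1%) lay more than 10 kb from any, with a median distance of 3950 bp.

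Within H3K27ac regions, H3K4me1 was centred on narrow regions and showed a shallow dip in the middle of those of 2 to 10 kb. In regions under 1 kb, 52.3% of midpoints lay in an H3K4me1 region, against 18.5% of positions 10 kb away. In regions of 1 to 2 kb the midpoint was again the most often covered position, at 68.7%. In regions of 2 to 4 kb, coverage was 74.2% at the midpoint and highest, 76.8%, at 0.6 kb to either side, a difference of 2.57 percentage points (95% bootstrap interval over regions 2.07 to 3.09). In regions of 4 to 10 kb it was 78.4% at the midpoint and 81.3% at 1.2 kb, a difference of 2.93 points (1.77 to 4.06). No dip was tested in the 444 regions of 10 kb or more, where coverage was 78.4% at the midpoint. The distance of the maximum was read from the same profile, so these intervals do not allow for that choice. A midpoint free of H3K4me1 with both edges covered was seen in 1440 of the 20450 regions of 2 to 4 kb (7.04%, interval 6.69% to 7.40%), while 1709 (8.36%) showed the opposite arrangement, a covered midpoint with neither edge covered.

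**Figure D2:**
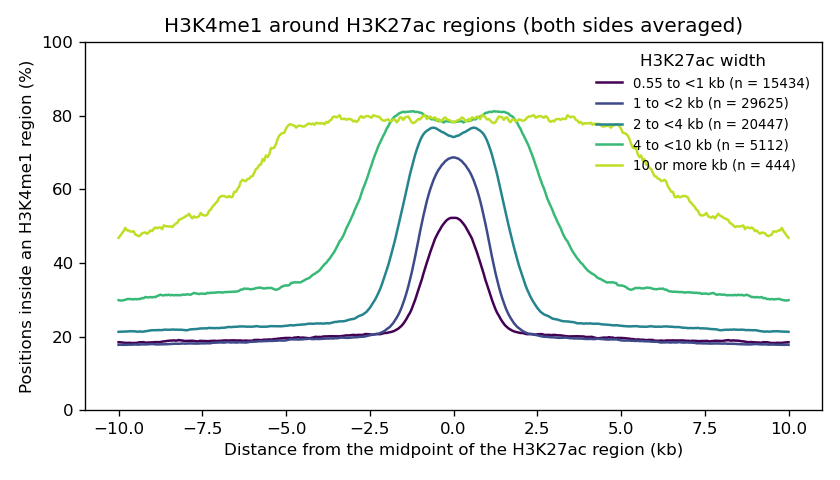
Percentage of positions inside an H3K4me1 region against distance in kb from the midpoint of H3K27ac regions, both sides averaged, by H3K27ac width. Curves for 2 to 4 kb and 4 to 10 kb are highest at 0.6 and 1.2 kb from the midpoint, 2.57 and 2.93 percentage points above it.

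The marks were spread unevenly over the chromosomes. Chromosome 17 was the densest for both, with 76.3 kb of H3K27ac and 184 kb of H3K4me1 per Mb, against 46.5 and 94.5 kb over all chromosomes. Chromosomes 19 (70.5 and 162 kb per Mb) and 1 (64.4 and 145 kb per Mb) followed. By span, chromosome 13 was the sparsest autosome, with 22.1 kb of H3K27ac and 34.5 kb of H3K4me1 per Mb, and chromosome 18 had 26.0 and 39.4 kb. Chromosome X had 22.0 kb of H3K27ac and 22.9 kb of H3K4me1 per Mb, and chromosome Y was the lowest of all at 5.21 and 4.31 kb. The spans include stretches without any region, of which 42 were 1 Mb or longer. Such stretches lower the density of a chromosome, so the order of the sparse chromosomes may not hold over sequenced length. LNCaP has an abnormal karyotype, and copy number was not corrected for here.

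The balance of the marks differed between chromosomes. The ratio of H3K27ac to H3K4me1 length was 0.492 over all chromosomes and ranged over the autosomes from 0.386 on chromosome 20 to 0.672 on chromosome 4. It was 0.961 on chromosome X and 1.21 on chromosome Y. Across the 22 autosomes the ratio was lower where H3K4me1 was denser (Spearman's rho -0.84, across chromosomes, which are not replicates, and with H3K4me1 in both quantities). Over windows of 1 Mb ranked by the length covered by either mark, the ratio did not fall steadily with density: it was 0.528 in the sparsest 291 of 2905 windows, 0.614 in the third group of this size and 0.455 in the densest 290. The share of H3K27ac regions overlapping H3K4me1 was highest on chromosome 22 (96.5%, interval 95.1% to 97.5%) and 19 (94.1%, 92.9% to 95.2%) and lowest among autosomes on chromosome 13 (72.1%, 69.6% to 74.5%). It was 63.1% (60.8% to 65.4%) on X and 51.7% (44.0% to 59.4%) on Y. The shifted means were 19.1% on chromosome 22, a 5.04-fold difference, 30.9% on chromosome 19, a 3.05-fold difference, 7.15% on chromosome 13, a 10.1-fold difference, and 5.23% on X, a 12.1-fold difference. The fold was largest on the sparsest chromosome, Y (75.6-fold), and smallest on the densest, 17 (2.69-fold). It therefore went with low density and does not by itself show closer coupling of the marks. Region-free stretches were not removed for single chromosomes.

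**Figure D3:**
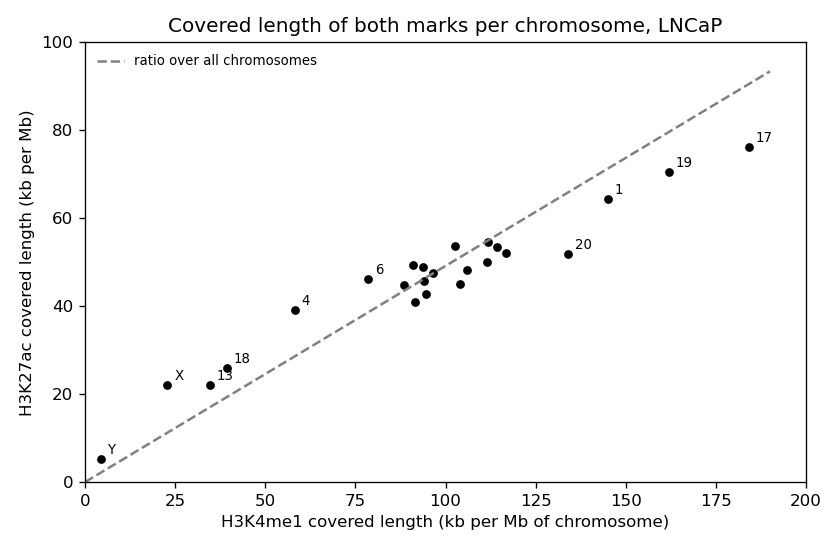
H3K27ac covered length against H3K4me1 covered length, both in kb per Mb of chromosome span, 1 point per chromosome; unlabelled points are the other autosomes and the dashed line is the ratio over all chromosomes, 0.492. Chromosomes X, 4, 13 and 18 lie above the line and chromosomes 17, 19, 20 and 1 below it.

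In windows of 1 Mb, the covered lengths of the marks rose together, with Spearman's rho 0.88 across the 2905 windows that held a region, as a description across windows of 1 library each. The median window held 40.0 kb of H3K27ac and 78.5 kb of H3K4me1. The windows richest in H3K27ac were at chromosome 21 from 17000001 to 18000000 with 485 kb, chromosome 4 from 102000001 to 103000000 with 292 kb, and chromosome 4 from 41000001 to 42000000 with 282 kb. The corresponding H3K4me1 lengths were 226, 112 and 265 kb, so H3K27ac exceeded H3K4me1 in each of these 3 windows, an excess that choosing by H3K27ac favours. The 3 windows richest in H3K4me1 had 496, 459 and 454 kb of H3K4me1 against 198, 160 and 176 kb of H3K27ac. Choosing by H3K4me1 favours this, and H3K4me1 was also the longer mark in the median window. Windows with H3K4me1 but no H3K27ac numbered 50, and held little H3K4me1. The highest was chromosome 5 from 83000001 to 84000000 with 15.8 kb, followed by chromosome 3 from 83000001 to 84000000 with 12.9 kb and chromosome 12 from 24000001 to 25000000 with 11.5 kb. Only 9 windows held H3K27ac without H3K4me1.

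Joining neighbouring H3K27ac regions gave 37027 clusters, of which 14641 held several regions and together 68.5% of all regions. Promoters were not removed before joining. The longest cluster lay at chromosome 21 from 17642501 to 17997450, where 44 regions covered 311 kb, or 87.7% of the span. The next were at chromosome 4 from 101931751 to 102272500 with 290 kb in 48 regions, chromosome 4 from 41358001 to 41673650 with 217 kb in 53 regions, chromosome 14 from 30178251 to 30406900 with 191 kb in 27 regions, and chromosome X from 44730001 to 44951350 with 179 kb in 26 regions. Ranks 6 to 10 were at chromosome 9 from 79234451 to 79532050 (178 kb), chromosome 8 from 102371301 to 102655300 (139 kb), chromosome 7 from 50652201 to 50890450 (136 kb), chromosome 12 from 64943151 to 65155100 (133 kb) and chromosome 8 from 134460151 to 134588900 (123 kb). Ranks 11 to 15 were at chromosome 8 from 128793251 to 128994650 (120 kb), chromosome 12 from 81841801 to 82022700 (118 kb), chromosome 3 from 57983251 to 58163750 (115 kb), chromosome 3 from 176752351 to 176931500 (115 kb) and chromosome 5 from 54711101 to 54833350 (110 kb). The 370 longest clusters, 1 in 100, held 11.6% of the H3K27ac length.

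The 15 longest clusters differed in how much H3K4me1 they carried. In the cluster of chromosome 21, H3K4me1 covered 42.4% of the H3K27ac length, and in the first cluster of chromosome 4, 32.4%. The lowest value, 23.2%, was at chromosome 12 from 81841801 to 82022700. Conversely, 96.2% was covered at chromosome 8 from 128793251 to 128994650 and 95.5% at chromosome 8 from 134460151 to 134588900, which H3K27ac covered over 95.8% of its span. Over all H3K27ac regions outside these 15 clusters the share was 71.7%.

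**Figure D4:**
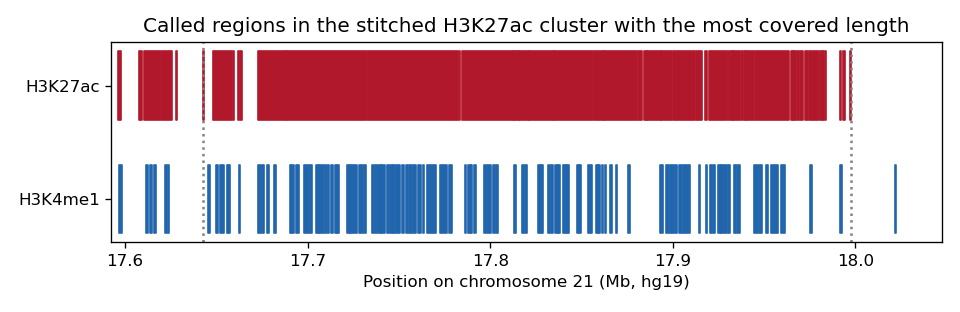
Called regions of H3K27ac (red) and H3K4me1 (blue) along chromosome 21 in Mb (hg19), with dotted lines at the ends of the cluster from 17642501 to 17997450. H3K27ac regions cover 87.7% of the cluster and H3K4me1 regions 38.1%.

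The widest single H3K27ac regions lay at chromosome 4 from 102072951 to 102194600 (122 kb, 32.6% of it in H3K4me1 regions), chromosome X from 44730001 to 44839750 (110 kb, 53.3%), chromosome 12 from 65000851 to 65093200 (92.4 kb, 89.1%), chromosome 22 from 46430351 to 46512350 (82.0 kb, 94.8%) and chromosome 15 from 89630151 to 89698050 (67.9 kb, 95.5%). The widest H3K4me1 regions lay at chromosome 19 from 13107101 to 13152350 (45.3 kb, 96.6% of it in H3K27ac regions), chromosome 9 from 137240501 to 137283350 (42.9 kb, 67.6%), chromosome 15 from 89640551 to 89678050 (37.5 kb, 100%), chromosome 14 from 100014251 to 100051350 (37.1 kb, 84.6%) and chromosome 14 from 105928201 to 105964850 (36.7 kb, 54.2%). The H3K4me1 region of chromosome 15 thus lay wholly inside 1 of the 5 widest H3K27ac regions.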

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

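The alternatives were fixed before the files were seen or added afterwards, and the latter are marked as added. Of 51 alternative values, 28 moved and 23 did not. A value moved when it left the interval of the main value, or changed more than 1.5-fold for counts and lengths. Reversal was not assessed, as a share, count or length cannot change sign. The share of H3K27ac regions overlapping H3K4me1, 83.1%, was 70.8% with an overlap of at least 50% of the region, 84.6% at scores up to the list median, 83.6% after merging within 1 kb, 83.6% on autosomes and 79.7% with H3K4me1 scores under 0.05, a setting added after seeing the data. The share of H3K4me1 regions overlapping H3K27ac, 34.5%, was 25.5% with the 50% overlap, 41.0% at scores up to the median and 42.2% with H3K4me1 scores under 0.05; merging and autosomes left it within its interval. The fold over shifted placements stayed above 1 throughout. It was 7.57 for H3K27ac and 5.20 for H3K4me1 with the 50% overlap, 5.60 and 5.97 at scores up to the median, 2.62 for both at the added fixed offset of 50 kb, and 3.81 for H3K27ac and 3.92 for H3K4me1 with region-free stretches removed, also added. Scores up to the median left 41859 H3K27ac and 101537 H3K4me1 regions outside the mitochondrial sequence. With the 50% overlap, the median width was 1250 bp for H3K27ac regions without H3K4me1 and 950 bp for H3K4me1 regions without H3K27ac. The H3K4me1 density of chromosome X relative to all chromosomes was 0.242 by length and 0.294 by number of regions. Spearman's rho between the marks was 0.83 in windows of 250 kb. The cluster of chromosome 21 stayed first with a joining distance of 5 kb and at scores up to the median, and under each of these settings 10 of the 15 longest clusters overlapped 1 of the new 15. Leaving out regions under 500 bp removed none. Alternatives for start sites and gene lists, and the removal of promoters before joining, were not run. No paired analysis was possible because each mark has 1 library. The unknown depth limits what can be said of regions absent from a list.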

Other observations

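The grouping of windows, the width excess and the 3 patterns with tests below were all found in the data, and only the tests of short breaks in H3K4me1 and of the score limit on chromosome X were written before any value bearing on them was seen. The tests of the lowest-scored regions, of other long clusters and of region density on X were written with some of their values already known. The bound for region width on X was restated after its result: as first written, an autosomal range met by at least 1 mark counted against fewer reads, which H3K27ac met, and it now reads as undecided because the marks part. Copy number and input reads were not used here, so they remain open for each pattern.

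When windows of 1 Mb were ranked by the length covered by either mark, the share of the H3K27ac length inside H3K4me1 regions rose as windows filled, and so did the share chance would give. In the sparsest 291 windows, with 9.08 kb covered per window, 31.6% of the H3K27ac length lay in H3K4me1 regions, and in the densest 290, with 301 kb per window, 84.0%. Independent placement of the marks within each window would give 0.737% and 28.2%, so the rise is not by itself a sign of closer coupling in dense windows. Relative to that placement the share fell, from 42.9-fold in the sparsest windows to 2.98-fold in the densest. The share cannot exceed the whole H3K27ac length, so the fold has a lower ceiling where the chance share is high. The fall therefore does not by itself show closer coupling in sparse windows. The H3K4me1 length inside H3K27ac regions rose less, from 16.7% to 38.2%. H3K27ac regions that met 3 or more H3K4me1 regions numbered 1713 and had a median width of 5300 bp, while 46410 met exactly 1.

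A set of 16 H3K4me1 regions carried the score 0.001, where the next score was 0.003, and 1 of them was the mitochondrial sequence. The other 15 included chromosome 10 from 42373301 to 42402750, chromosome 1 from 121481851 to 121486000, chromosome 19 from 27731351 to 27740800 and chromosome 18 from 18510501 to 18520900. These had the highest H3K27ac coverage of the set, 98.6% or more of their length. Over the 15 the coverage ranged from 50.9% to 100%, and 9 had 90% or more. The median H3K27ac coverage of the 15 was 96.4%, above all 1000 sets of H3K4me1 regions of matched width (median 59.5%, highest 87.8%), as a pile-up of reads shared by any library would give, though strong enhancers would give it too. Against strong enhancers as the source of the whole set, 7 of the 15 lay within 1 Mb of a stretch of 1 Mb or more without any region, where matched sets had a median of 0 and at most 3. A candidate explanation is read pile-up in repeats at the edges of assembly gaps, which stays untested without the input library and remains open in particular for the other 8 regions.

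Pooled over the 15 longest clusters, H3K4me1 covered 62.3% of the H3K27ac length, against a median of 77.3% in 1000 sets of 15 clusters of ranks 16 to 370 (central 95% from 64.8% to 86.7%, lowest set 55.0%; 68.1% to 87.7% when weighted by the lengths of the 15). The 15 were mixed, with 4 under 50% and 3 over 90%, and ranks 1 and 2 held 375 of the 934 kb without H3K4me1. The pooled share without ranks 1 and 2 was not compared with the sets, so the departure may rest on these 2 clusters. Choosing the 15 by H3K27ac length can also favour an excess of H3K27ac. Of the 355 comparison clusters, 22 had a share as low as rank 1 and 16 as low as rank 2. Breaks of 1 kb or less in H3K4me1 region calling account for little, as 14.4% of the H3K27ac length without H3K4me1 lay in such H3K4me1-free stretches. Stretches over 5 kb held 40.8%, the longest being 23.4 kb. The rest lay in stretches between 1 and 5 kb, and breaks in calling of that length were not tested. A hypothesis that remains is that the marks truly part within some of these domains, but weak H3K4me1 signal below the calling threshold cannot be excluded from the lists.

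H3K27ac was long relative to H3K4me1 on chromosome X, with a ratio of 0.961 (bootstrap over windows 0.855 to 1.08, treating neighbouring windows as independent). Low density as such does not explain it, since autosomal windows matched on the length of either mark gave 0.528 (central 95% from 0.482 to 0.577, highest of 1000 sets 0.618). The sets pooled windows of all autosomes, so their spread leaves out differences between chromosomes. The highest whole autosome, chromosome 4, had 0.672, above every set but below X. Regions with scores of 0.02 or more do not explain it either. With both lists under a score of 0.02 the ratio on X was 1.13 and the highest autosome, chromosome 4, had 0.762. The same score need not mean the same stringency in both lists, so unequal calling of the marks was not excluded. Fewer reads per locus on X were not excluded: H3K4me1 regions on X had a mean width of 1197 bp, below the 1293 bp of the lowest autosome, while the mean H3K27ac width of 1949 bp lay inside the autosomal range of 1884 to 2395 bp. The share of regions above the list's median score on X lay inside the autosomal range for both marks. It was 49.6% for H3K4me1 (range 42.7% to 51.8%) and 39.9% for H3K27ac (range 29.4% to 46.0%). Fewer reads could also drop weak regions from the lists, so this share cannot speak for or against fewer reads. A biological difference of X was not tested. Chromosome Y had a higher ratio still, 1.21, and was not examined in these tests.

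Widths piled up at 1050 bp in both lists, with 2850 H3K27ac regions of that width against 1993 at 1000 bp and 1455 at 1100 bp, and 13982 H3K4me1 regions against 9454 and 4949. The excess over both neighbouring widths was present on 22 of 22 autosomes in each list. The narrowest width, 550 bp, held 3053 H3K27ac and 16492 H3K4me1 regions.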
